A study of Apis mellifera with 6 samples.

How the data were processed

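RNA sequencing of honey bee (Apis mellifera) midgut was re-analysed in 6 samples, 3 from bees fed 24 µM tunicamycin in sucrose solution with 0.5% DMSO (dimethyl sulfoxide, the solvent) and 3 from bees fed 0.5% DMSO alone, each for 24 hours. Per the labels, midguts were stored in RNAlater, RNA was extracted with Trizol, mRNA was selected by poly(A), and libraries made with a NEBNext Ultra kit were sequenced on an Illumina HiSeq instrument. The submitters' processing notes name Trimmomatic 0.36, STAR, Subread and DESeq2. The role and settings of each tool and the genome build are not given in the sources used here, and neither is the strand setting of the counting, so overlapping and antisense genes and near-identical gene copies can share reads.

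The authors deposited 3 tables, each with a control and a tunicamycin sample, and the same 10013 genes in each. The deposited values are a normalized signal, gene read counts divided by a size factor for each sample. This was read from the values: in all 6 columns 100% of the values were whole multiples of the worth of 1 read, within a tolerance of 0.001 of a read. In control 1 that worth is close to 1 and rests on large values, which depart from whole numbers while staying whole multiples of it. The median ratio of each sample to the geometric mean over samples was 1.0030 in all 6, so the samples share a joint scaling of the type DESeq2 makes and can be compared across the 3 tables. The recovered reads came to between 22763496 and 26278751 per sample over the listed genes. The lowest mean normalized value of a gene was 9.89, and 9983 genes had a value above 0 in every sample.

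The design fixed before the data were examined assumed read counts and named edgeR. Since the tables held normalized values, the test it gave for that case was the main test: limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1) with all 6 samples and the group as the sole term, and a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes, and every adjusted p printed is from this limma model unless another tool is named. A filter on a mean value of at least 1 removed 0 genes. The recovered reads were tested with edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and limma-voom as alternatives. Other alternatives were a pseudocount of 0.1, a mean of at least 1 CPM (read counts scaled to library size), TMM, upper-quartile and RLE scaling, a block by deposited table, a block by shared replicate number, a fold threshold of 2, and each sample left out in turn. The fold change of each deposited pair was taken from TMM-scaled CPM with a prior count of 2 and checked with 0.5. The labels do not say that the replicates came from separate cages or colonies, so the p-values measure only the spread between these samples, which may be technical.

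On simulated data with the real genes' means and library sizes, limma-trend called 39.0% of genes set to change 2-fold and 80.0% of those set to change 4-fold over the 10013 genes of this comparison, with 4 false calls among 123. DESeq2 called 63.0% and 90.0%, with 34 false calls among 187. The simulated genes varied independently, with as many falls as rises and no sample set apart from its group, so these shares may not hold for the real samples.

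Of the 10013 gene identifiers, 303 (symbols) carry a name and 9710 (97.0%) are LOC numbers. A reference table of the assembly Amel_HAv3.1 matched 9205 identifiers (91.9%) and was used for biotypes, synonyms and the order of neighbouring genes; 808 did not match, among them the entry 6-Mar, which looks like a symbol turned into a date by a spreadsheet. The table gives no product descriptions, so LOC numbers were not named. The 23 gene lists fixed beforehand could therefore be filled by symbol alone: 13 had a match and 10 had none. Those without a match were the sensors and regulators of the unfolded protein response, degradation and translocation at the endoplasmic reticulum (ER), ER-Golgi trafficking, cell death and autophagy, cytosolic ribosomal proteins, membrane lipid synthesis, cell cycle, Malpighian tubule and ileum markers, and tracheal markers. IRE1, XBP1, PERK, ATF6, ATF4, GRP94, calreticulin, SEL1L, HRD1, derlins and ALG7 were not analysed here by name. Another 8 lists were added by symbol family after the values were seen.

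Lists with at least 5 members (11, of which 3 were fixed beforehand) were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 11 lists. The named genes were, by a rule fixed beforehand, regulators and chaperones of the unfolded protein response where measured by name, the 10 largest rises and falls past the threshold with a name, a log2 mean CPM of at least 1 and the same direction in all 3 deposited pairs, up to 4 members per list (those past the threshold by smallest p or, where fewer than 2 passed, up to 2 with the largest change), and at most 2 LOC numbers in each direction. Further members of the fixed lists, and all genes of the added lists, were chosen after their values were seen.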

Results

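The deposited tables gave normalized read counts of 10013 genes in the midgut of honey bees fed tunicamycin, an inhibitor of the first step of N-glycosylation that causes misfolded proteins to build up in the ER, or its DMSO solvent. There were 3 control samples (replicates 1, 2 and 3) and 3 tunicamycin samples (replicates 2, 3 and 4). Depth was similar across samples, at 23305215, 26278751 and 24808957 recovered reads in controls 1, 2 and 3 and 22763496, 25025084 and 24120622 in tunicamycin samples 2, 3 and 4. The most abundant gene took between 8.9% and 13.1% of the reads of a sample. Correlations between samples (Pearson, log2 values, across genes) lay between 0.956 and 0.979. Replicates of a group differed by more than the noise of read counting alone (chi-square per degree of freedom over genes between 45.4 and 180.8).

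The comparison of tunicamycin with control asks which midgut genes respond to the inhibitor, in a study titled for the IRE1 branch of the unfolded protein response. Hsc70-3, the ER chaperone BiP and a classical target of that response, rose 6.66-fold by the difference of mean log2 values. Its arithmetic means were 42977 ± 22567 normalized reads in controls and 265545 ± 52623 in tunicamycin (mean ± SD, n = 3 each; log2 fold change 2.73, SE 0.40; limma adjusted p = 0.0279). MsrA, a methionine sulfoxide reductase that repairs oxidized methionine, rose 7.48-fold by the same measure, with arithmetic means of 716 ± 204 and 5403 ± 1813 (log2 2.90, SE 0.28; limma adjusted p = 0.00786). CytC, the electron carrier cytochrome c, rose from 4712 ± 1383 to 11963 ± 1463 (log2 1.38, SE 0.21; limma adjusted p = 0.0335), and ecd, named for the ecdysoneless mutant of flies, rose from 411 ± 46.8 to 748 ± 84.8 (log2 0.86, SE 0.14; limma adjusted p = 0.0438). All 4 were higher in each tunicamycin sample than in any control.

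Across all genes the response was mostly upward. Of the 10013 genes, 106 were higher and 7 lower in tunicamycin at a limma adjusted p under 0.05, and 1557 had an unadjusted p under 0.05. The higher genes had a median fold of 2.73 and ranged from 1.55-fold to 36.1-fold; 77 of them rose at least 2-fold and 24 at least 4-fold. All 113 had the same direction in the 3 deposited pairs of a control and a tunicamycin sample, which their choice from these samples nearly fixes. Hsc70-3, MsrA, CytC and ecd were the 4 with a symbol, and the other 109 were LOC numbers. The largest rises among these 113 genes were those of LOC410087, from 1371 ± 331 to 53785 ± 31251 normalized reads (log2 5.17, SE 0.37; limma adjusted p = 0.00404), and LOC552832, from 368 ± 102 to 13841 ± 7556 (log2 5.13, SE 0.38). The largest fall among them was that of LOC107965774, at 243, 261 and 267 normalized reads in controls 1, 2 and 3 and 0, 1.06 and 4.72 in tunicamycin samples 2, 3 and 4 (limma adjusted p = 0.00661); it was 1 of 21 genes near 0 in some libraries and well above in the others. LOC100577039 fell by 3.90 on the log2 scale (SE 0.65; limma adjusted p = 0.0444), with 351 reads in control 1 against 98.6 and 71.9 in controls 2 and 3. Protein-coding genes made up 99 of the higher and 6 of the lower genes, out of 8415 tested. Of 738 long non-coding RNAs, 3 were higher and 1 was lower. Their median log2 mean CPM was 0.87, against 4.38 for protein-coding genes, so these counts do not compare the response alone.

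**Figure D1:**
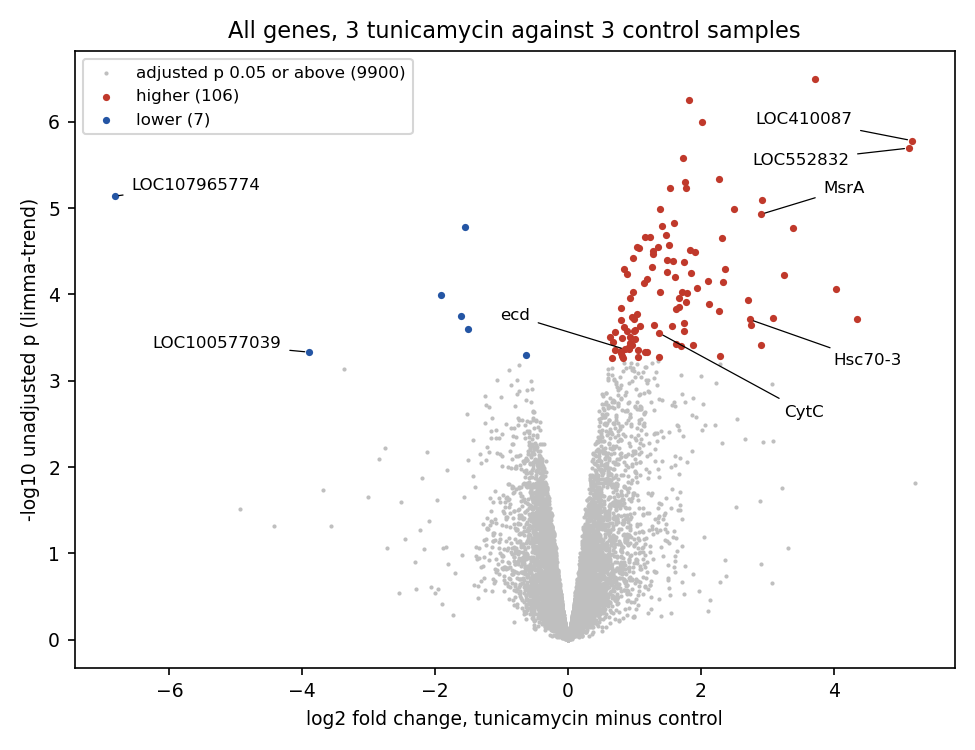
Each point is a gene, with the log2 fold change of tunicamycin over control on the x axis and -log10 of the unadjusted limma-trend p on the y axis; red points are the 106 higher and blue points the 7 lower genes at an adjusted p under 0.05. Hsc70-3 lies at 2.73, MsrA at 2.90, CytC at 1.38 and ecd at 0.86, and LOC107965774 lies farthest to the left at -6.82.

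Control 1 stood apart from controls 2 and 3. It lay at 48.7 on the second principal component (25.1% of the variance), against -21.3 and -14.3, and held 68417 normalized reads of Hsc70-3 against 35140 and 25372. Tunicamycin sample 3 differed from its group too. On the first component (31.6% of the variance) it lay at 6.2, against 28.6 and 35.8 for tunicamycin samples 2 and 4. Its chi-square per degree of freedom was 180.8 and 172.6 against those samples, which had 103.4 between them. Without control 1, limma called 180 genes higher and 22 lower, and the adjusted p of Hsc70-3 was 0.010. Without control 2, control 3, tunicamycin 2, tunicamycin 3 or tunicamycin 4 it called 23, 20, 57, 99 and 32 genes in all. The calls of Hsc70-3, CytC, ecd and LOC100577039 were kept without control 1 and lost when any other sample was left out, while those of MsrA, LOC410087, LOC552832 and LOC107965774 were kept in all 6 such fits. With edgeR on the recovered reads CytC had an adjusted p of 0.0501 and LOC100577039 of 0.058. DESeq2 on the recovered reads called 516 genes, of which 401 were higher and the rest lower, including all 113 of the limma calls.

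Over all 13 fixed lists with a match, 1 of 41 genes (Hsc70-3) passed in limma and in edgeR over all genes. An unadjusted limma p under 0.05 was found for 8 of the 41, against 1557 of all 10013 genes. In DESeq2 6 of the 41 passed, against 516 of 9790 genes. The other genes that passed in DESeq2 were Ppib, Hsc70-5, Cbs and Trxr-1, with higher values in tunicamycin, and Hbg3, with lower ones (adjusted p = 6.20e-04, 8.17e-04, 0.00586, 0.00973 and 0.0278).

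In the ER chaperone list, 2 members could be matched by symbol. Hsc70-3 passed over all genes, and both passed when adjusted over the list alone. Ppib, the ER cyclophilin B, was at 8763 ± 1118 in controls and 13855 ± 758 in tunicamycin (log2 0.67, SE 0.14; limma adjusted p = 0.0878), which over 20 alternatives ranged from 6.20e-04 (DESeq2) to 0.313 and passed in 2 of them. The list of cytosolic and mitochondrial heat shock proteins had 3 members and none passed over all genes; 1 passed when adjusted over the list alone. That member was Hsc70-5, the mitochondrial HSP70, at 5205 ± 267 and 9855 ± 2395 (log2 0.89, SE 0.19; limma adjusted p = 0.0939). The cytosolic chaperones Hsc70-4 (log2 0.19, SE 0.24) and Hsp90 (log2 -0.21, SE 0.43) differed by less than the spread between replicates, and Hsp90 was at 46743 normalized reads in control 1 against 21939 and 12954 in controls 2 and 3. Neither N-glycosylation gene passed over all genes or when adjusted over the list alone: STT3B, a catalytic subunit of the oligosaccharyltransferase, was at log2 0.20 (SE 0.16) and Gfat2, the entry enzyme of the hexosamine pathway, at log2 -0.20 (SE 0.34). The single matched member of the ATF4-type amino acid list, Cbs (cystathionine beta-synthase), was at log2 0.58 (SE 0.12; limma adjusted p = 0.0878 over all genes), and it passed when adjusted over the list alone, where no adjustment is made for 1 gene.

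**Figure D2:**
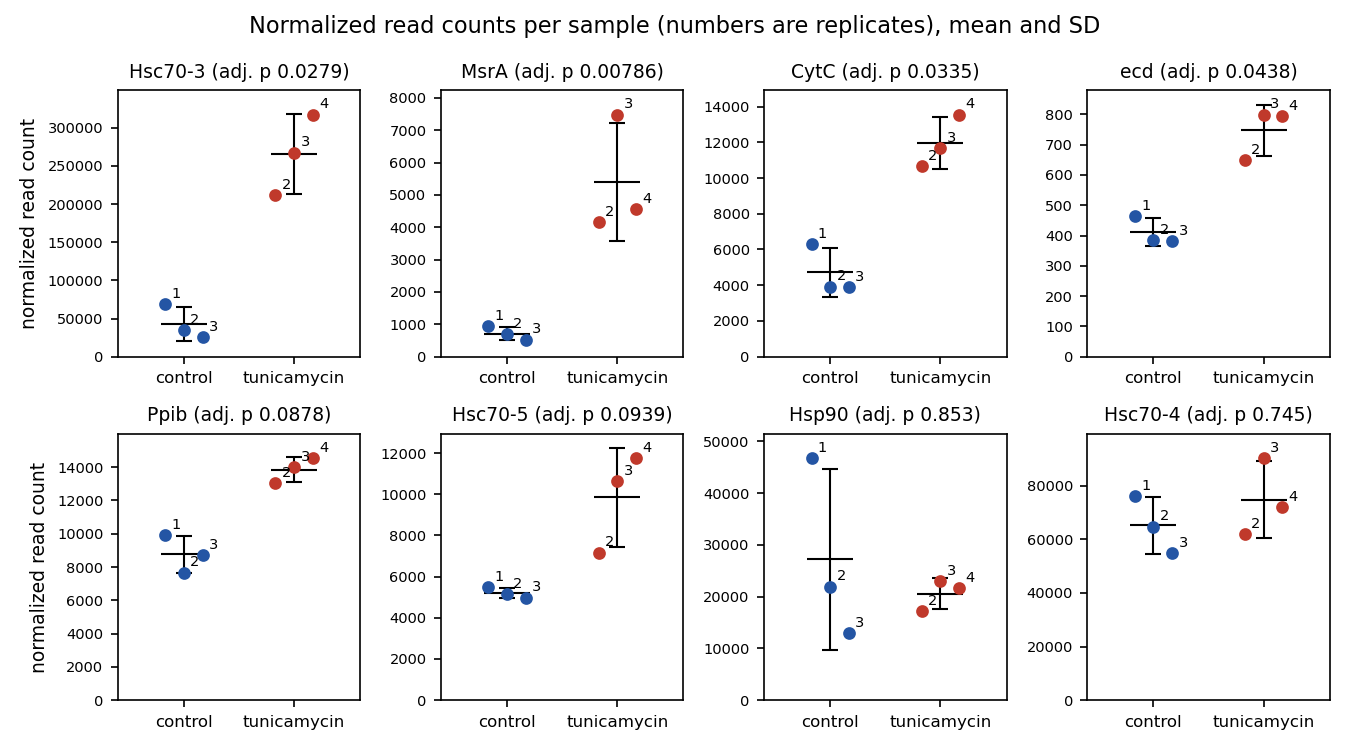
Normalized read counts (y axis, from 0) of 8 genes in the control and tunicamycin samples, with 1 point per sample numbered by replicate and a line and bar for the mean and SD of 3 samples. Hsc70-3 lies between 25372 and 68417 in controls and between 211942 and 317129 in tunicamycin, while the groups overlap for Hsp90 and Hsc70-4.

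None of the 6 oxidative stress genes passed over all genes, and 1 passed when adjusted over the list alone. This was Trxr-1, thioredoxin reductase, at 12678 ± 1362 and 18614 ± 1907 (log2 0.55, SE 0.15; limma adjusted p = 0.150). Catalase (Cat) was at log2 0.48 (SE 0.21), and the superoxide dismutase Sod1 at log2 0.19 (SE 0.16). The list as a whole did not pass (camera adjusted p = 0.427; fry adjusted p = 0.0506). Among 3 digestive enzymes, all alpha-glucosidases that split dietary sugars, none passed over all genes, and Hbg3 was lower when adjusted over the list alone, at 1504 ± 298 and 846 ± 215 (log2 -0.84, SE 0.23; limma adjusted p = 0.163). AGLU2 (log2 -0.46, SE 0.47) and Hbg2 (log2 -0.30, SE 0.55), at 668191 ± 68278 and 669161 ± 193382 normalized reads in controls, did not pass (limma adjusted p = 0.673 and 0.838). The glutathione transferases GstD1 (log2 -0.20, SE 0.23) and GstS1 (log2 -0.32, SE 0.21), the 2 members of the detoxification list, did not pass over all genes or when adjusted over the list alone.

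The 7 immune genes included none that passed, over all genes or when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.708). Pgrp-s2, a peptidoglycan recognition protein, was at log2 -0.89 (SE 0.41), and the antimicrobial peptide gene Def1 was at log2 -0.63 (SE 0.87), with 296 normalized reads in control 1 against 57.7 and 19.4 in controls 2 and 3. Rpn1, the single match of the proteasome list, was at log2 -0.35 (SE 0.17) and did not pass over all genes or when adjusted over the list alone; the symbol is used both for a proteasome subunit and for ribophorin I.

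Among markers of other tissues and cell types no gene passed in limma, edgeR or DESeq2. Of 8 fat body and hypopharyngeal gland genes none passed over all genes or when adjusted over the list alone (camera adjusted p = 0.617); Hex70a, a hexamerin storage protein, was at log2 -0.80 (SE 0.23; limma adjusted p = 0.176) and Mrjp8, of the royal jelly protein family, at log2 -0.32 (SE 0.29). The muscle genes TpnI (log2 0.22, SE 0.32) and TpnT (log2 0.37, SE 0.29), the hemocyte gene PPO (log2 -0.22, SE 0.25) and the enteroendocrine and neuronal genes Tk (log2 0.52, SE 0.21), NPF (log2 0.34, SE 0.26) and Syt1 (log2 0.19, SE 0.37) did not pass over all genes or when adjusted over the list alone.

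**Figure D3:**
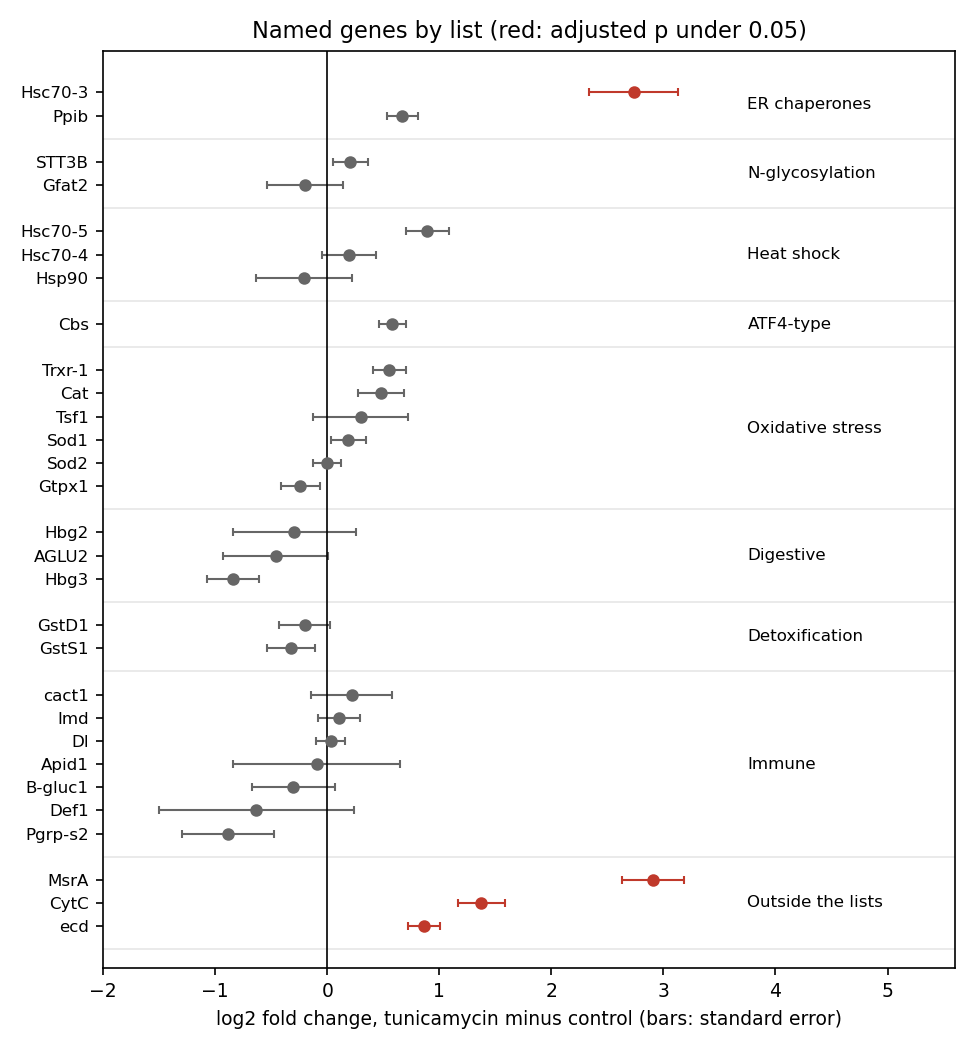
Log2 fold change of tunicamycin over control (x axis) with its standard error (bars) for the matched genes of 8 fixed lists and for MsrA, CytC and ecd, which belong to none of them (n = 3 samples per group). Red points passed a limma adjusted p under 0.05 over all genes: Hsc70-3, MsrA, CytC and ecd.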

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

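The limma block by deposited table, limma on TMM- and upper-quartile-scaled reads, the added lists and the count of splits were chosen after seeing the data. The use of edgeR with TMM scaling as an alternative was also chosen then. The design had named it beforehand as the main test for read counts, with a block by deposited table as its alternative. All 113 genes called by limma kept their sign in every alternative, which their choice from these same samples nearly fixes. The counts stayed within 1.5 times of 113 genes, 106 of them higher, with a pseudocount of 0.1, a mean CPM of at least 1, limma-voom, edgeR with TMM, RLE and upper-quartile scaling or no filter, limma on TMM- and upper-quartile-scaled reads, and a fold threshold of 2. DESeq2 called 516 genes, 401 of them higher; in the simulation it also made more false calls (34 against 4), and the cause was not tested. With 1 sample left out the counts ranged from 20 to 202 genes, 18 to 180 of them higher. The 202 (180 higher, 22 lower) came without control 1; without tunicamycin sample 3 there were 84 higher and 15 lower. Fewer genes were called without control 2 (23), control 3 (20), tunicamycin 2 (57) or tunicamycin 4 (32). Deviations of samples in the same table correlated at 0.05, 0.15 and 0.05, against -0.12 to 0.06 across tables. In 4 of 6 samples the partner correlated best, so pairing stays open. With the replicate block by deposited table limma called 44 genes (41 higher) and edgeR 38 (36 higher). The replicate block by shared number, with 4 samples and 1 residual degree of freedom, called 4 genes, all higher (limma; 0 lower, 1054 genes at an unadjusted p under 0.05). The calls of Hsc70-3, CytC, ecd and LOC100577039 were lost with each block (limma adjusted p = 0.101, 0.106, 0.16 and 0.139 by table), and those of MsrA and LOC107965774 in the 4-sample fit alone (0.0832 and 0.0695).

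Of 160 alternatives for the 8 genes past the threshold, 42 lost the call. The direction changed in 0, which the choice of these genes from the same samples nearly fixes. Hsc70-3 passed in 12 of 20, with adjusted p from 1.72e-11 to 0.135. Of 1350 for the other named genes, 24 gave a call, 16 of them with DESeq2. Of 110 alternatives for the gene lists, 1 changed the call: cuticular proteins passed with the replicate block by deposited table (adjusted p = 0.0429, against 0.106, and adjusted p = 0.617 with an estimated correlation). For the lists, RLE scaling was not run, because the deposited scaling is already of that type, and the low-value filter removes 0 genes, so that its omission tests nothing. Of the 10 splits of the 6 samples into 3 and 3, the real one called 113 genes and the highest other 1, so that 1 split, the real one itself, gave as many; 10 splits are too few for a share under 0.05. At this depth and 3 samples a group the simulation, in which no sample stood apart, recovered 39.0% of 2-fold changes.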

Other observations

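The gene groups of the next paragraph were picked by symbol after the values were seen. So were the tests of mixed RNA at the induced genes, of a weaker response at the genes 2-fold away in control 1, and of the splits of on/off genes. The test of neighbour levels by their median and quartiles was set beforehand. Its reading by what all moved reads would raise was not part of that prediction.

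Of 10 ecdysone and juvenile hormone genes, ecd passed over all genes, and E75, Jhe and ecd passed when adjusted over the list alone (list: camera adjusted p = 0.118; adjusted p = 0.617 with an estimated correlation). E75, an ecdysone-induced nuclear receptor, was at 18885 ± 3502 in controls and 36546 ± 7522 in tunicamycin (log2 0.95, SE 0.22; limma adjusted p = 0.110), and Jhe, juvenile hormone esterase, at 3100 ± 579 and 1445 ± 604 (log2 -1.17, SE 0.29; limma adjusted p = 0.128). The silk gene Fibroin4 was at 49.3 ± 16.2 and 223 ± 135 (log2 2.04, SE 0.43; limma adjusted p = 0.0901). Of 11 cuticular protein genes 9 had a positive fold change, with CPR27 at log2 1.65 (SE 0.39), and the list did not pass (camera adjusted p = 0.106; adjusted p = 0.617 with an estimated correlation). All 7 ribosomal protein genes had a positive fold change, led by Rpl39 at log2 0.81 (SE 0.19; limma adjusted p = 0.110), and the list did not pass either (camera adjusted p = 0.106; adjusted p = 0.617 with an estimated correlation). CytC was the single respiratory chain gene of 8 that passed; the list had a median log2 fold change of -0.12, a mean of 0.07, and camera and fry directions that differ (camera adjusted p = 0.779). Odorant-binding and chemosensory proteins (12 genes, median 0.10, mean -0.17, camera direction down, adjusted p = 0.875), neurotransmitter receptors (18, adjusted p = 0.516), microRNA genes (30, adjusted p = 0.427) and troponins (7, adjusted p = 0.875) did not pass by camera, and none of their genes passed over all genes in limma or edgeR. Of the 30 microRNA genes, in libraries selected by poly(A), 5 had an unadjusted limma p under 0.05, against 1557 of all 10013 genes. In DESeq2 2 of them passed, Mir6060 (log2 1.20, SE 0.37) and Mir9888 (log2 1.19, SE 0.32). Of the 18 receptors 2 had an unadjusted limma p under 0.05. E75, Jhe, Fibroin4, Rpl39 and CPR27 passed in DESeq2 on the recovered reads (adjusted p = 9.98e-04, 0.0101, 1.62e-04, 0.00698 and 0.0449), and Rpl39 and CPR27 passed when adjusted over their lists alone.

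Control 1 differed by at least 2-fold from the mean of controls 2 and 3 in 956 genes, with Hsc70-3 at 2.26 times and Hsp90 at 2.68 times that mean. The count was 520 and 505 for controls 2 and 3 set beside their own remaining controls. For tunicamycin samples 2, 3 and 4 set beside the rest of their group it was 626, 693 and 507. RNA of a tunicamycin sample mixed into control 1, or a weaker response of the tunicamycin kind, would place most of the 956 genes between the other controls and tunicamycin. Of them, 736 (77.0%) lie outside the range between those means by more than 0.5 on the log2 scale. This share alone cannot decide on either explanation. Genes chosen as 2-fold away in controls 2 and 3 gave shares close to it (74.6%, 388 genes, and 71.5%, 361 genes). Neither explanation by itself would add genes outside the range, and control 1 had 736 there against 388 and 361. These counts argue against either as the whole account of the 956 genes. Inside the range control 1 had 220 genes, against 132 and 144, so a part for either stays open. Hsp90 is outside that range too, at 46743 normalized reads in control 1 against 17217, 22930 and 21632 in tunicamycin samples 2, 3 and 4. At the genes that tunicamycin raised, both explanations stay open. The linear scale was used for 26 genes at least 4-fold higher in tunicamycin, chosen without control 1. There control 1 lay a median 11.7% of the way from the mean of controls 2 and 3 to the tunicamycin mean (quartiles 3.7% and 16.3%, Hsc70-3 16.2%). Over the 100 top genes of a fit without control 1, it lay at a median log2 position of 0.34 between the other controls (0) and tunicamycin (1). Controls 2 and 3 lay at -0.01 and -0.05 by the same measure, and their baseline includes control 1. The tests do not separate a mixture from a weaker response there, and no label gives control 1 another history.

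LOC107965774 was 1 of 21 genes near 0 (at most 20 normalized reads) in some libraries and at 50 or more, at least 16 times higher, in the others; 12 of the 21 had no match in the reference table. Whether tunicamycin feeding sets its pattern stays open, because 4 such genes split the samples 3 against 3, of which 1 followed the groups and the highest other split also held 1. Reads assigned to a neighbouring gene in the libraries near 0 would raise that neighbour there. The 18 measured neighbours differed by a median of -0.05 on the log2 scale (quartiles -0.77 and 0.02). The lower quartile lay beyond the bound of 0.5 set beforehand, so this test did not decide. Of the 11 neighbours that all moved reads would raise by at least 0.5, the highest differed by 0.14. This argues only against all the reads moving to those 11. It leaves open the 7 more abundant neighbours, among them LOC409793 beside LOC107965774. The unmatched genes, and neighbours that are unlisted or unmatched, stay open too. Pban, a neuropeptide gene and another of the 4, held 599, 1029 and 16.5 normalized reads in controls 1, 2 and 3 and 988, 13.7 and 13.2 in tunicamycin samples 2, 3 and 4. Some on/off genes followed the deposited pairs, which bears on the open question of pairing. LOC100576440 was near 0 in control 1 and tunicamycin 2 alone, and LOC100576880 in control 2 and tunicamycin 3 alone. LOC100576452 and LOC102656264 were near 0 in all but control 2 and tunicamycin 3. LOC100578075, LOC552666 and LOC727570 were each near 0 in 2 libraries from different tables. The main test has no term for the pairs. Inherited differences between the sampled bees were not tested.

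A hypothesis was tested that responding genes are clustered in the genome. Among 103 higher genes placed by Amel_HAv3.1, there were 4 side-by-side pairs that do not overlap, 1 of them holding Hsc70-3, against a mean of 0.95 in 10000 permutations of the calls (permutation p = 0.0153, one-sided). Shared regulation, tandem copies that share reads, or reads running past the end of a neighbour may each give such pairs, and these were not told apart.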
